A study of Mus musculus with 12 samples.

How the data were processed

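RNA from livers of Abcb4(-/-) and Abcb4(+/+) mice was measured on Agilent 4x44K whole mouse genome arrays, with knockout and wild type on the same array in different dyes. Per the labels, 5 livers per diet group were harvested and nothing was pooled. In 3 hybridizations per group the wild type was in Cy3 and in the others it was in Cy5, 1 of these being a dye swap of a liver already used. This gave 6 arrays per group on 5 slides: slides 1 and 2 held CA arrays 1 to 4, slide 3 held CA array 5 with UDCA arrays 1 and 2, slide 4 held CA array 6 with UDCA arrays 3 to 5, and slide 5 held UDCA array 6. Sex, strain, age, the diet of the wild-type mice, the doses of the bile acids and the hour of sampling are not given in the sources used here.

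Per the file headers, the images were read with Feature Extraction 9.5.3, which gave the mean intensity of each spot and the median intensity of its local background in green and red without normalization. The same program also gave, per the file headers, processed signals after background subtraction, detrending and dye normalization, and their log10 ratio of red over green. The deposited series values give 1 log2 ratio per probe and array. On bright spots these log2 values correlated with those of the scanner files with an absolute Pearson correlation between 0.970 and 0.996, and the sign of the CA columns was opposite to that of knockout over wild type, so it was turned before use. How the series table was normalized is not given in the sources used here. Probe positions are those of the scanner files, in mm7. The wider study may hold other data, which were not used here.

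The raw intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Of 45018 spots, 1639 control spots were left out, and the 43379 others gave 41174 probes after spots of the same probe were averaged. Values flagged by the scanner software as non-uniform or population outliers were set to missing (2399 of 260256 values of tested probes, 0.922%). A probe was kept if it was well above background in at least 5 of 6 arrays in either channel of either group. This kept 21693 probes, of which 21688 had enough values to be tested. Gene symbols came from a RefSeq table through the accession for 15542 tested probes, and the other 6146 kept the name in the scanner file. The tested probes made 15373 names, 12382 of them symbols in the table. A gene was represented by its brightest tested probe. Of 128 called values of genes taken by the naming rule that had another tested probe, all other probes were called in the same direction for 105, another probe was not called for 22, and another was called in the opposite direction for 1.

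The comparisons were CA-fed knockout against wild type, UDCA-fed knockout against wild type, and the difference between these. They were fitted together with limma on the log2 ratios, with a dye effect per probe and an empirical Bayes variance (9 residual and 5.95 prior degrees of freedom, prior standard deviation 0.30). A probe was called at an adjusted p under 0.05. The dye effect itself was called for 2790 probes. The difference between the diets is indirect, because each side was measured against wild-type liver on its own arrays. To find the technical dye swap, the residuals of the fit were correlated for the 9 possible pairs per group. The highest correlation was 0.141 in the CA group and 0.105 in the UDCA group, under the limit of 0.3 fixed before the data were examined, so all 6 arrays were kept and each counted as a replicate. As a consequence, 1 pair per group shares a liver and the p-values are slightly too small.

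The 35 gene lists, fixed before the data were examined from textbook knowledge, held 599 genes, of which 530 were measured. They were tested with camera at its preset correlation, against all other genes, and again with a correlation estimated from the data. The rotation test fry was used for movement in one direction, which does not compare a list with other genes. At an adjusted p under 0.05, camera with the preset correlation called 65 of 105 tests, camera with an estimated correlation called 0 (19 unadjusted), and fry called 29 lists with CA, 24 with UDCA and 22 in the difference. In the male-biased list 5 genes stand in another list too, and in those of bile acid synthesis, uptake, complement and coagulation, cytochrome P450s and glutathione 1 gene each. Members were also counted after adjustment over their list alone, the higher ones being given before the lower ones.

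The genes named in the text were taken by a rule fixed before the data were examined. For each comparison it took the 10 largest rises and 10 largest falls among called genes with the same direction on all 6 arrays or, for the difference, with no overlap between the diets, and up to 4 called members with the largest change from each list. It always took Abcb4, Cyp7a1, Cyp8b1, Abcb11, Slc10a1, Nr0b2, Col1a1, Timp1, Krt19, Ccl2, Lcn2, Mki67 and the Y-linked genes. The values of 1 gene under this rule are not reported here. For a gene whose wild-type signal was not well above background, the ratio was read as a bound. Genes of near-identical families, such as those of Hsd3b, Mup, Cyp2b, Cyp2c, Saa and Gst, may share signal on a 60-base probe, and which member was measured is uncertain.

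Alternatives fixed beforehand were no background correction, the scanner software's own ratios, median centring in place of loess, scaling between arrays, no filter and a strict filter, no dye term, a fit of each group alone, leaving out each array, averaging each possible dye-swap pair, a block for the slide, a block for the replicate number, the series table, camera with an estimated correlation and the mean of all probes of a gene. After the data had been seen, 3 more were added: leaving out 3 arrays with a dim red channel, setting saturated spots to missing (2919 tested probes had such a value and 1011 were left out for too few others), and the slide as an additive term. The slide as a block means a separate dye effect for each slide, which does not remove a shift of the ratios shared by a slide. CA arrays 1 and 2 and UDCA array 6 lay on slides with a single dye orientation. They carry no weight in the estimates of that fit.

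With 6 arrays per group, precision was limited. In data simulated from the measured spread (20318 probes), a log2 change of 0.5 was recovered for 47.0% of probes in the CA comparison, 51.5% in the UDCA comparison and 18.9% in the difference, and a change of 1 for 94.0%, 97.0% and 82.8%. False calls made up 5.85%, 4.07% and 3.94% of all calls there. Only 66 or 67 probes per group were given each size of change, whereas 59.6%, 23.5% and 27.0% of probes were called in the data. The adjusted threshold is stricter where fewer probes change, so these shares do not give the power of the reported fit. Within a group, arrays with the same dyes correlated at 0.486 to 0.883 and arrays with opposite dyes at 0.0189 to 0.754. The first principal component of the ratios held 38.2% of the variance and the second 26.3%. Of the called probes, 97.2% in the CA comparison, 98.2% in the UDCA comparison and all but 4 of 5858 in the difference had the same sign with either dye orientation. Single channels were compared as a check on the wild-type side: between CA and UDCA arrays 14 probes differed in the wild-type channel (4959 unadjusted) and 7663 in the knockout channel.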

Results

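Liver RNA of Abcb4(-/-) mice was set against liver RNA of Abcb4(+/+) mice on 12 Agilent whole mouse genome arrays read in 2 colours. Abcb4 is the canalicular transporter that brings phospholipid into bile, and mice without it develop a bile duct disease used as a model of sclerosing cholangitis. For 9 weeks the diet of the knockout mice had held either of a pair of bile acids, cholic acid (CA) or ursodeoxycholic acid (UDCA). Per the series' design text, CA was given to raise disease activity and UDCA to lower it. UDCA has one hydroxyl group fewer than CA and carries another in the opposite orientation. Each diet group held 5 knockout livers on 6 arrays, 3 with the knockout in Cy5 and 3 with it in Cy3, one of the latter being a technical dye swap. The labels give neither the doses nor the diet of the wild-type mice, and they do not say which arrays form the dye swap. All knockout livers on these arrays came from mice fed CA or UDCA. A ratio to wild type therefore holds the loss of Abcb4 and the bile acid together. Median green intensity per array ranged from 250.2 to 1296 and median red intensity from 59.2 to 158.2. Between 41.6% and 68.4% of spots were well above background in green and between 31.6% and 62.4% in red. After the filter on dim probes, 21688 probes were tested, covering 12382 genes with a current symbol. Signed values are log2 ratios of knockout over wild type on the same array, given with the standard error of the limma fit (6 arrays from 5 livers per diet), and adjusted p-values are Benjamini-Hochberg values over all tested probes. Levels could be measured in arbitrary intensity only, and the number of arrays limits the precision.

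The knocked-out gene was lower than wild type in both groups, although not on every array for every probe. The brighter Abcb4 probe, A_51_P249118 (mm7, chromosome 5, 8996752 to 8996811), read -0.78 ± 0.20 in CA-fed liver (adjusted p = 0.00377, lower on 5 of 6 arrays) and -1.26 ± 0.20 in UDCA-fed liver (adjusted p = 0.000300, lower on 5 of 6 arrays). Its ratios on CA arrays 1 to 6 were 0.11, -0.44, -0.52, -0.95, -1.46 and -1.43, and on UDCA arrays 1 to 6 they were -1.01, 0.35, -1.90, -1.86, -1.36 and -1.80. The spot was saturated on 4 CA arrays. The second Abcb4 probe, A_52_P223194 (mm7, chromosome 5, 8978600 to 8978659), was lower on all 12 arrays, at -2.54, -3.16, -2.60, -3.73, -2.25 and -2.07 with CA and -1.88, -1.49, -1.40, -1.89, -1.20 and -2.77 with UDCA. The sources used here do not say whether either probe lies in the deleted part of the gene, so a remaining signal says nothing about the genotype.

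CA-fed knockout liver, set against wild-type liver, had more RNA of matrix, bile duct, chemokine and cell division genes. It had less RNA of many genes for bile acid synthesis and uptake and for cholesterol, fatty acid and drug metabolism. Camera with an estimated correlation called none of these lists. Collagen genes and the biliary transcription factor gene Sox9 rose, and Cyp7a1 and Cyp8b1, which encode enzymes that make bile acids, fell. The receptor gene of incoming monocytes, Ccr2, rose, while Clec4f, a gene of resident Kupffer cells, fell. In all, 7387 probes were higher and 5543 lower than in wild type, and 2418 of the higher and 1088 of the lower ones changed at least 2-fold. Counted once per gene, 4884 genes were higher and 2785 lower. Among genes with the same direction on 6 of 6 arrays, the 10 with the largest rises were Sparcl1 (4.83 ± 0.19), a matricellular protein, Fhl2 (4.58 ± 0.27), Clec7a (4.31 ± 0.14), a lectin receptor of myeloid cells, Anxa3 (4.29 ± 0.28), Ccr2 (4.15 ± 0.29), the receptor that brings monocytes to Ccl2, Cx3cl1 (4.14 ± 0.26), Rragd (4.06 ± 0.23), Tbx1 (4.03 ± 0.24), the collagen receptor kinase Ddr1 (3.88 ± 0.21) and the matrix proteoglycan Lum (3.82 ± 0.21). The 10 largest falls were those of the liver collectin Colec10 (-4.95 ± 0.23), the pseudogene Serpina4-ps1 (-4.69 ± 0.31), Wfdc21 (-4.65 ± 0.30), Hsd3b4 (-4.28 ± 0.18), Cyp8b1 (-4.17 ± 0.24), Upp2 (-3.80 ± 0.19), Cyp2c54 (-3.72 ± 0.18), Slc17a8 (-3.69 ± 0.19), the major urinary protein gene Mup5 (-3.52 ± 0.27) and Hsd3b5 (-3.48 ± 0.27). The limma adjusted p-values of these 20 genes lay between 1.96e-10 and 5.52e-08. Other probes of Ccr2 (1.04) and Rragd (1.39 and 1.94) were called higher too but rose less.

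Many genes of bile acid synthesis, uptake and sensing fell in CA-fed knockout liver. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.96 on the log2 scale (adjusted p = 1.86e-05, lower on 6 of 6 arrays). Cyp8b1 (mm7, chromosome 9, probe at 121617140 to 121617199), which adds the hydroxyl group that distinguishes CA, fell by 4.17, and the oxysterol hydroxylase gene Cyp7b1 fell by 2.80. In all, 8 of 15 bile acid synthesis genes fell and 0 rose (0 and 8 adjusted over the list alone; camera adjusted p = 7.63e-05, adjusted p = 0.226 with an estimated correlation). All 7 of 7 uptake carriers of bile acids and organic anions fell (0 and 7 adjusted over the list alone; camera adjusted p = 0.000385, adjusted p = 0.215 with an estimated correlation), among them the bile acid carrier Slc10a1 at -1.94 ± 0.25 and Slco1a1 at -2.60. Export went both ways: 4 of 11 carriers rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.585), and the list's median of -0.11 and mean of 0.24 differed in sign. The basolateral exporters Abcc4 (2.62, its other probe, also called, at 0.60) and Slc51b (2.19) rose, the cholesterol exporter Abcg8 (-1.36) fell, and the bile salt export pump Abcb11 gave -0.11 ± 0.27 (adjusted p = 0.736). Of 11 bile acid receptors and sensors, 7 fell and 1 rose (1 and 7 adjusted over the list alone; camera adjusted p = 0.00334, adjusted p = 0.226 with an estimated correlation). Nr1i3 was at -1.97, the FGF co-receptor Klb at -1.58, the bile acid receptor Nr1h4 at -0.95 and the repressor Nr0b2 at -0.87.

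Matrix and bile duct genes rose in CA-fed knockout liver. Among 36 fibrosis and extracellular matrix genes 32 rose and 0 fell (33 and 0 adjusted over the list alone; camera adjusted p = 2.85e-09, adjusted p = 0.203 with an estimated correlation), led by Lum, Ccn2 (3.54), Col6a3 (3.37) and the microfibril gene Fbn1 (3.07). The collagen gene Col1a1 was at 3.06 ± 0.30 and the protease inhibitor gene Timp1 at 0.99 ± 0.13. Stellate cell and portal fibroblast markers gave 14 rises and 0 falls in 16 (14 and 0 adjusted over the list alone; camera adjusted p = 2.52e-05, adjusted p = 0.185 with an estimated correlation). Pdgfrb was at 3.00, Pdgfra at 2.89 and vimentin, Vim, at 2.87. For cholangiocyte and ductular reaction markers, 18 of 20 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 2.19e-06, adjusted p = 0.226 with an estimated correlation). Sox9, the transcription factor of biliary cells, was at 3.69, Epcam at 3.57, Pkhd1 at 3.48 (its other probes, also called, at 0.77 and 1.60), Bicc1 at 3.48 and Krt19 at 2.76 ± 0.20. Endothelial markers, as another cell type of the tissue, had a median of 0.13, with 6 of 13 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.458), and Cd34 at 3.12 was the largest change. Oncofetal and progenitor genes gave 8 rises and 2 falls in 10 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0578), among them a pair of genes active in fetal liver, Afp (1.26) and H19 (1.39). Ly6d was at 2.98, Mdk at 2.15 and the growth factor Igf2 at 1.55.

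Chemokine and antigen presentation genes rose in CA-fed knockout liver, and macrophage genes moved both ways. Of 22 macrophage and Kupffer cell markers, 14 rose and 6 fell (15 and 6 adjusted over the list alone; camera adjusted p = 0.0856). The monocyte receptor Ccr2 (4.15), Cd14 (3.73) and Trem2 (3.72) rose, while Clec4f, a lectin of Kupffer cells, fell by 3.37 (adjusted p = 2.09e-08, lower on 6 of 6 arrays). Cd5l (-2.19), Vsig4 (-1.54) and the scavenger receptor gene Cd163, also genes of tissue macrophages, fell as well. Chemokines and cytokines gave 18 rises and 0 falls in 20 (19 and 0 adjusted over the list alone; camera adjusted p = 2.26e-05, adjusted p = 0.226 with an estimated correlation). Cx3cl1 was at 4.14, Ccl20 at 3.03, Cxcl16 at 2.93 and Ccl2 at 1.69 ± 0.38. All 10 of 10 MHC class II genes rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.000231, adjusted p = 0.233 with an estimated correlation), among them Ctss (2.74) and H2-DMb1 (2.49). T and NK cell markers gave 6 rises and 2 falls in 12 (6 and 2 adjusted over the list alone; camera adjusted p = 0.457). B and plasma cell markers gave 4 and 0 in 6 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.334 with an estimated correlation). Blnk was at 2.18. Only 3 of 14 neutrophil markers were measured, and 2 rose and 0 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.528). Interferon response genes gave 10 rises and 4 falls in 18 (10 and 4 adjusted over the list alone; camera adjusted p = 0.122). Oasl2 was at 2.16 and Gbp3 at 1.86.

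Cell division genes rose together: 28 of 30 were higher and 0 lower (28 and 0 adjusted over the list alone; camera adjusted p = 8.47e-09, adjusted p = 0.185 with an estimated correlation). The replication helicase gene Mcm6 was at 3.22, the proliferation marker Mki67 at 3.06 ± 0.17 and Birc5 at 2.41. In the list of p53 targets and immediate early genes, 14 of 16 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 0.000113, adjusted p = 0.226 with an estimated correlation). The early response factor Egr1 was at 3.83, the p53 target Phlda3 at 2.46 and Gadd45b at 2.38.

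Many metabolic genes fell in CA-fed knockout liver. Cholesterol synthesis genes fell in 21 of 25 cases and rose in 1 (1 and 22 adjusted over the list alone; camera adjusted p = 2.85e-09, adjusted p = 0.185 with an estimated correlation). Insig1 was at -2.60 and Stard4 at -2.24. Fatty acid synthesis genes gave 14 falls and 0 rises in 18 (0 and 14 adjusted over the list alone; camera adjusted p = 2.19e-06, adjusted p = 0.185 with an estimated correlation). The acetyl-CoA carboxylase gene Acacb was at -3.28 and the glycolytic enzyme gene Pklr at -2.15. In fatty acid oxidation 14 of 22 genes fell and 2 rose (2 and 14 adjusted over the list alone; camera adjusted p = 0.000232, adjusted p = 0.233 with an estimated correlation), Cyp4a10 falling by 2.57 while Vnn1 (2.64) and Pdk4 (2.07) rose. Xenobiotic cytochrome P450 genes showed 13 falls and 1 rise in 21 (1 and 13 adjusted over the list alone; camera adjusted p = 6.01e-06, adjusted p = 0.233 with an estimated correlation), from Cyp2c54 (-3.72) and Cyp2c38 (-3.06) to Cyp2c55 (1.27), the member that rose. Glutathione and NRF2 antioxidant genes went both ways, 5 of 21 up and 4 down (4 and 4 adjusted over the list alone; camera adjusted p = 0.278). Acute phase genes fell in 10 of 23 cases and rose in 3 (3 and 10 adjusted over the list alone; camera adjusted p = 0.0127, adjusted p = 0.334 with an estimated correlation). Orm1 was at -1.82 and Orm2 at -1.70 but Lcn2 at 2.23 ± 0.16. In complement and coagulation 11 of 25 genes fell and 0 rose (0 and 11 adjusted over the list alone; camera adjusted p = 2.90e-05, adjusted p = 0.254 with an estimated correlation). The complement gene C8b was at -1.06 and the clotting factor gene F9 at -1.32. The 11 include Mbl2, which in the CA group had values in a single dye orientation. General hepatocyte genes gave 4 falls and 0 rises in 22 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00286, adjusted p = 0.462 with an estimated correlation). Glul was at -1.55, and 21 of the 22 were saturated on 3 or more CA arrays. The same held for 18 of 25 complement and coagulation genes, 14 of 21 P450 genes, 11 of 21 antioxidant genes, 9 of 15 bile acid synthesis genes, 5 of 7 uptake carriers and 10 of 14 male-biased genes. Genes with higher expression in male liver fell in 10 of 14 cases (0 and 10 adjusted over the list alone; camera adjusted p = 2.19e-06, adjusted p = 0.185 with an estimated correlation), although 5 members of this list stand in another list too. Genes with higher expression in female liver gave 6 falls and 3 rises in 12 (3 and 6 adjusted over the list alone; camera adjusted p = 0.0879).

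Genes of the pancreas, fixed as a check for tissue from a neighbouring organ, were also lower in the CA group, in 4 of 4 cases (0 and 4 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.381 with an estimated correlation). Their median ratio was -3.65 on CA array 3 and -3.30 on CA array 4, which shared a slide, and between -0.73 and -0.13 on the other 4 CA arrays. Arrays 3 and 4 are also a possible dye-swap pair, with the highest residual correlation of the CA group (0.141), so they may come from 1 liver. Without CA replicate 3 the list's adjusted p was 0.0527, and without CA replicate 4 it was 0.0553, within a range of 0.00288 to 0.0646 over all settings with the preset correlation. The digestive enzyme gene Amy2 was at -2.01 ± 0.29 (adjusted p = 2.61e-05). Of the Y-linked genes, 1 of 4 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.278), namely Ddx3y at -0.46 ± 0.15, whose other probe read -0.02 and was not called. With the slide as a block, CA arrays 1 and 2 carry no weight in the estimates. In that fit 7 of 10 MHC class II genes were called higher, their median going from 1.23 to 0.67. The number of lower hepatocyte genes went from 4 to 10, and the median of the acute phase genes went from -0.41 to -0.21 and that of the pancreas genes from -1.47 to -2.28. Camera with an estimated correlation called 0 of 35 lists in this comparison, and 8 had an unadjusted p under 0.05. With each array centred on its median in place of loess, 4942 probes were higher and 1152 lower. The median over all tested probes then lay at 0.24 in place of 0.04.

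**Figure D1:**
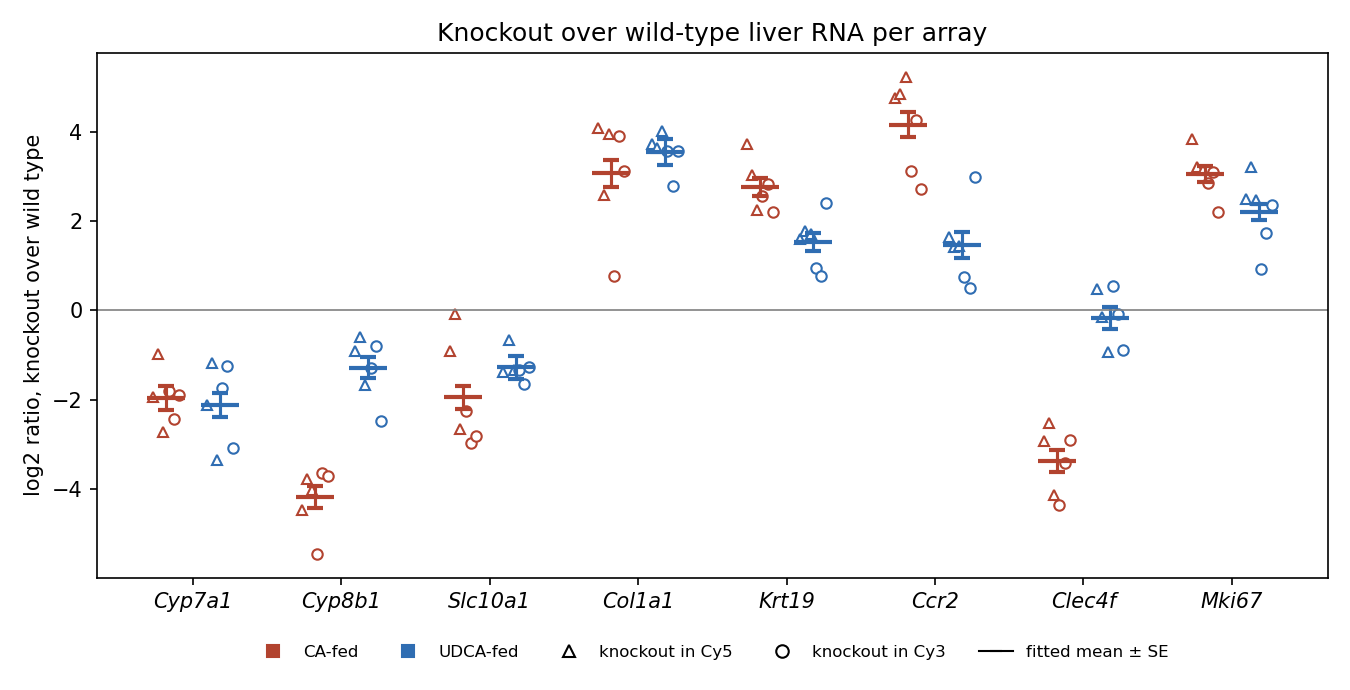
Log2 ratios of knockout over wild-type liver RNA for 8 genes, with 1 open symbol per array (triangles for the knockout in Cy5, circles for the knockout in Cy3), 6 arrays each for CA-fed (red) and UDCA-fed (blue) livers, and bars for the fitted mean ± standard error. Cyp7a1 lies near -2 in both groups (-1.96 and -2.11), while Cyp8b1 and Clec4f lie lower and Ccr2 lies higher in CA-fed than in UDCA-fed liver.

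UDCA-fed knockout liver also had more RNA of many matrix, bile duct and cell division genes than wild-type liver. Many genes of the antioxidant response rose, among them Srxn1, which repairs oxidized peroxiredoxins, and Gclc, which starts glutathione synthesis. Most genes of cholesterol synthesis fell, as did some of bile acid synthesis, among them Cyp7a1. The lipid droplet gene Cidec and the fatty acid carrier gene Cd36 rose. In the test against wild type 3294 probes were higher and 1807 lower, 699 and 294 of them at least 2-fold, and per gene the numbers were 2384 and 1066. Among genes with the same direction on 6 of 6 arrays, the largest rises were those of the collagen gene Col1a1 (3.55 ± 0.30; mm7, chromosome 11, probe at 95060800 to 95060859; its other probe at 0.77), Ifi27l2b (3.46 ± 0.23), the basement membrane gene Nid1 (3.43 ± 0.20), the keratin gene Krt23 (3.30 ± 0.20), Bicc1 (3.18 ± 0.23), Fhl2 (3.18 ± 0.27), Ndrg1 (3.08 ± 0.15), Cd36 (3.06 ± 0.17), Cidec (3.06 ± 0.21) and Mgp (3.05 ± 0.32). The largest falls were those of Hsd3b4 (-4.74 ± 0.18), Serpina4-ps1 (-4.35 ± 0.31), Hsd3b5 (-4.10 ± 0.27), Adgrv1 (-3.96 ± 0.16), Upp2 (-3.79 ± 0.19), Lrtm1 (-3.18 ± 0.25), the organic anion carrier Slc22a7 (-3.17 ± 0.23), Rdh16f2 (-3.12 ± 0.18), Colec10 (-2.94 ± 0.23) and Cyp7b1 (-2.87 ± 0.25). The limma adjusted p-values of these 20 lay between 1.35e-09 and 5.44e-06. Of the 10 rises 9 were called in the same direction with CA, and of the 10 falls all 10 were.

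Some genes of bile acid synthesis and uptake also fell with UDCA, while most of the called exporters rose. Cyp7a1 was at -2.11 ± 0.27 (adjusted p = 4.05e-05, lower on 6 of 6 arrays) and Cyp8b1 at -1.28 ± 0.24 (adjusted p = 0.000984, lower on 6 of 6 arrays). Bile acid synthesis genes gave 6 falls and 0 rises in 15 (0 and 6 adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.251 with an estimated correlation). Of the 7 uptake carriers, 3 fell and 1 rose (1 and 4 adjusted over the list alone; camera adjusted p = 0.00777, adjusted p = 0.230 with an estimated correlation), the latter being Slco1a4 at 1.41, while Slc10a1 was at -1.27 ± 0.25. Exporters rose in 6 of 11 cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0501). Abcc4 was at 2.14 (its other probe, not called, at 0.07) and Abcc3 at 1.69, and Abcb11 gave -0.02 ± 0.22 (adjusted p = 0.955). Receptors and sensors gave 4 falls and 1 rise in 11 (1 and 6 adjusted over the list alone; camera adjusted p = 0.00571, adjusted p = 0.230 with an estimated correlation). Nr0b2 was at -0.76.

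Matrix genes rose in 25 of 36 cases and fell in 0 (30 and 0 adjusted over the list alone; camera adjusted p = 8.62e-13, adjusted p = 0.101 with an estimated correlation). The fibrillar collagen gene Col3a1 was at 2.93 (its other probe, not called, at 0.14), Lum at 2.74 and Timp1 at 0.48 ± 0.13. Stellate cell and portal fibroblast markers gave 11 rises and 0 falls in 16 (12 and 0 adjusted over the list alone; camera adjusted p = 1.38e-06, adjusted p = 0.0938 with an estimated correlation). Cholangiocyte and ductular markers gave 13 rises and 1 fall in 20 (14 and 1 adjusted over the list alone; camera adjusted p = 1.53e-06, adjusted p = 0.184 with an estimated correlation). Spp1 was at 2.02 and Krt19 at 1.53 ± 0.20. Endothelial markers had a median of 0.10, 2 of 13 rising and 1 falling (3 and 1 adjusted over the list alone; camera adjusted p = 0.283). Oncofetal and progenitor genes gave 5 rises and 1 fall in 10 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0418, adjusted p = 0.253 with an estimated correlation).

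Macrophage and Kupffer cell markers rose in 14 of 22 cases and fell in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 0.000154, adjusted p = 0.203 with an estimated correlation). Trem2 (2.96), Lyz1 (2.64) and Cd14 (2.50) rose, Cd5l (0.59) and Vsig4 (0.62) rose where they had fallen with CA, and Clec4f gave -0.17 ± 0.24 (adjusted p = 0.670). Among the 2 that fell was Cd163 (-1.61), a gene of tissue macrophages that had fallen with CA too. Chemokines and cytokines gave 12 rises and 0 falls in 20 (15 and 0 adjusted over the list alone; camera adjusted p = 5.52e-06, adjusted p = 0.184 with an estimated correlation). Ccl2 was at 2.22 ± 0.38 and the lymphotoxin gene Ltb at 1.97. Of 10 MHC class II genes 7 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.000484, adjusted p = 0.230 with an estimated correlation). T and NK cell markers gave 2 rises and 1 fall in 12 (2 and 1 adjusted over the list alone; camera adjusted p = 0.525). For B and plasma cell markers the numbers were 1 and 0 in 6 (1 and 0 adjusted over the list alone; camera adjusted p = 0.283), and for neutrophil markers 1 and 0 in 3 (2 and 0 adjusted over the list alone; camera adjusted p = 0.357). Interferon genes gave 6 rises and 2 falls in 18 (8 and 3 adjusted over the list alone; camera adjusted p = 0.211). Cell division genes rose in 26 of 30 cases and fell in 0 (26 and 1 adjusted over the list alone; camera adjusted p = 3.88e-13, adjusted p = 0.0898 with an estimated correlation). Kif20a was at 2.42 and Mki67 at 2.20 ± 0.17. Of 16 p53 targets and immediate early genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 2.22e-05, adjusted p = 0.184 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was at 2.23.

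Among metabolic genes, cholesterol synthesis fell in 16 of 25 cases and rose in 0 (0 and 18 adjusted over the list alone; camera adjusted p = 1.74e-11, adjusted p = 0.0898 with an estimated correlation). Stard4 was at -1.85. Fatty acid synthesis gave 5 falls and 0 rises in 18 (0 and 7 adjusted over the list alone; camera adjusted p = 3.66e-05, adjusted p = 0.184 with an estimated correlation). For fatty acid oxidation the numbers were 7 and 3 in 22 (3 and 7 adjusted over the list alone; camera adjusted p = 0.0230, adjusted p = 0.412 with an estimated correlation). Vnn1 was at 2.40 and Pdk4 at 2.12. Glutathione and NRF2 antioxidant genes rose in 15 of 21 cases and fell in 0 (16 and 0 adjusted over the list alone; camera adjusted p = 9.11e-07, adjusted p = 0.0938 with an estimated correlation), among them the peroxide-repair gene Srxn1 (2.15) and the glutathione transferase genes Gsta2 (1.73) and Gsta1 (1.60). Xenobiotic cytochrome P450 genes gave 5 falls and 3 rises in 21 (4 and 6 adjusted over the list alone; camera adjusted p = 0.0600), from Cyp2c54 (-2.37) to Cyp2b10 (1.92) and Cyp2c55 (3.81). Acute phase genes rose in 6 of 23 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.226). Lcn2 was at 2.35 ± 0.15 and the serum amyloid gene Saa3 at 1.59. Complement and coagulation genes gave 4 falls in 25 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00301, adjusted p = 0.399 with an estimated correlation). General hepatocyte genes gave 3 falls in 22 (0 and 3 adjusted over the list alone; camera adjusted p = 0.00301, adjusted p = 0.480 with an estimated correlation), 20 of the latter being saturated on 3 or more UDCA arrays. Male-biased genes fell in 9 of 14 cases (0 and 9 adjusted over the list alone; camera adjusted p = 2.68e-07, adjusted p = 0.0938 with an estimated correlation). Female-biased genes rose in 6 of 12 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.230 with an estimated correlation). Cyp2b9 was at 2.43 ± 0.34 and Cyp2b13 at 2.31 ± 0.21. Pancreas genes changed in 0 of 4 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.826), with a median of -0.02 and a mean of 0.17. The counts of lower metabolic genes with UDCA changed when each slide was given its own dye effect. UDCA array 6 carries no weight in the estimates of that fit, so its loss and the slides cannot be told apart. With the slide as a block, the lower genes went from 3 to 15 of 22 for hepatocyte genes (median -0.32 to -0.74) and from 4 to 14 of 25 for complement and coagulation (-0.26 to -0.51). They went from 5 to 12 of 21 for P450 genes, with 2 higher (-0.35 to -0.67), and from 6 to 10 of 15 for bile acid synthesis (-0.30 to -0.84). For uptake carriers they went from 3 to 5 (-0.56 to -0.91), for fatty acid synthesis from 5 to 11 and for fatty acid oxidation from 7 to 4. The median went from 0.66 to 0.36 for female-biased genes and from 0.13 to -0.06 for acute phase genes. Camera with an estimated correlation called 0 of 35 lists in this comparison, and 8 had an unadjusted p under 0.05. With median centring in place of loess 1870 probes were higher and 101 lower. The median over all tested probes then lay at 0.30 in place of 0.03.

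**Figure D2:**
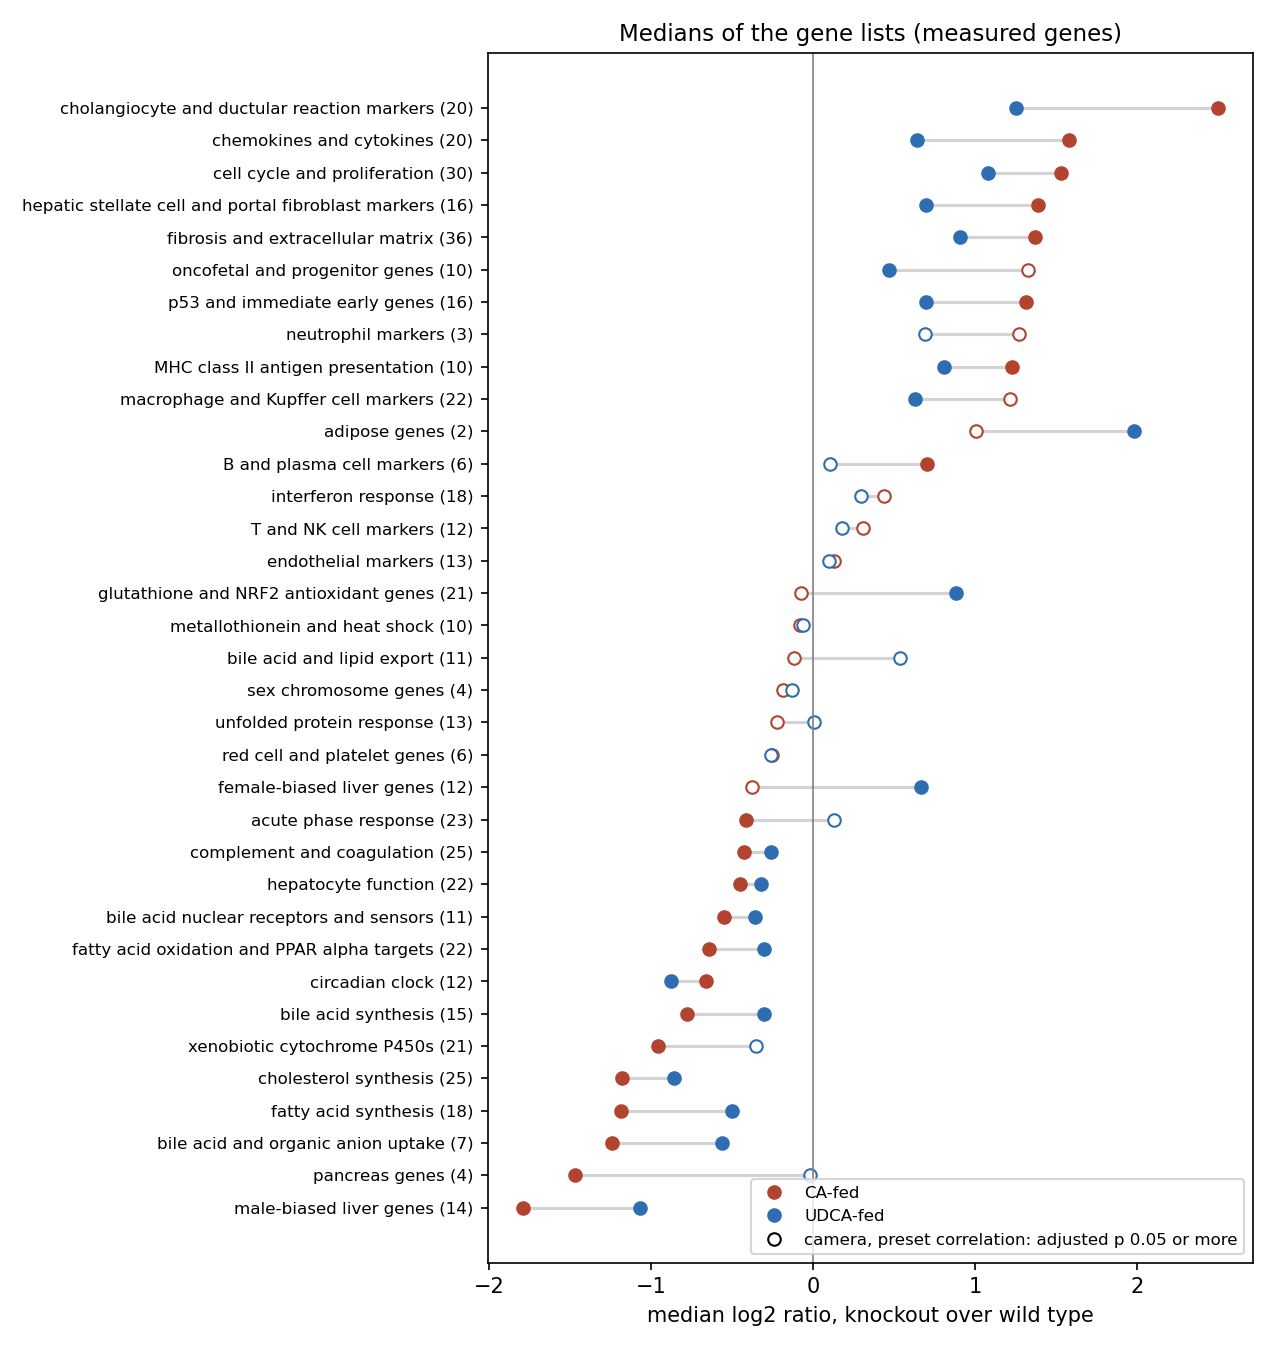
Median log2 ratio of knockout over wild type for each of the 35 gene lists, with the number of measured genes in brackets, in CA-fed (red) and UDCA-fed (blue) liver; filled points passed camera with the preset correlation and open points did not. Cholangiocyte markers lie highest with CA (2.50, against 1.25 with UDCA), and glutathione and NRF2 antioxidant genes lie at -0.07 with CA and 0.88 with UDCA.

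Between the diets, 13 of 20 bile duct genes, 18 of 36 matrix genes and the monocyte receptor gene Ccr2 were higher with CA than with UDCA. Many antioxidant genes, some drug metabolism genes and the Kupffer cell genes Clec4f and Cd5l were lower with CA. Camera with an estimated correlation called none of the gene lists here. Cyp8b1 was lower with CA, while Cyp7a1 was not shown to differ. In the test of the difference, CA minus UDCA on the ratios to wild type, 3542 probes were higher and 2316 lower with CA, 1121 and 437 of them at least 2-fold, which made 2468 and 1163 genes. Of these 5858 probes, 5382 had the larger change against wild type with CA and 476 with UDCA. Because the doses are not given in the labels, the values stand side by side without a matched dose. Among genes whose arrays did not overlap between the diets, the largest positive differences were those of the cadherin gene Celsr1 (3.01 ± 0.21), the chemokine gene Ccl12, the transcription factor gene Bcl6 (2.97 ± 0.51), the apoptosis gene Bmf (2.90 ± 0.41, its other probe, not called, at 0.34), Tbx1 (2.72 ± 0.33), Tmem130 (2.57 ± 0.33), Ms4a6b (2.55 ± 0.26), the chloride channel gene Cftr, Grhl2 (2.46 ± 0.32) and Sox9 (2.43 ± 0.30). No difference is printed for Cftr and Ccl12, because the wild-type signal was not well above background on any array for Cftr and on any UDCA array for Ccl12. Their places in this ranking rest on the same ratios and are uncertain. The ratio of Cftr with CA is a bound of at least 7.69-fold, and with UDCA neither Cftr (adjusted p = 0.0595) nor Ccl12 (adjusted p = 0.160) was called against wild type. The largest negative differences were those of the cytochrome P450 genes Cyp2b9 (-4.66 ± 0.47; mm7, chromosome 7, probe at 23107426 to 23107485) and Cyp2b13 (-3.64 ± 0.30), Wfdc21 (-3.86 ± 0.42), Clec4f (-3.20 ± 0.34), Cyp8b1 (-2.89 ± 0.34), Cd5l (-2.78 ± 0.24), Cidec (-2.74 ± 0.30), the carboxylesterase genes Ces2c (-2.61 ± 0.31) and Ces1f (-2.56 ± 0.41) and the pancreatic elastase gene Cela1 (-2.44 ± 0.69). Cela1 stood at -3.75 and -3.85 on CA arrays 3 and 4, which shared a slide and may share a liver, and between -0.50 and 0.42 on the other CA arrays. Chance separates 2 sets of 6 arrays for 0.216% of genes and 2 sets of 5 livers for 0.794%, and the limma adjusted p-values lay between 3.80e-06 and 0.0167.

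Some genes moved in opposite directions against wild type. There were 60 genes lower with CA and higher with UDCA, and 37 genes higher with CA and lower with UDCA, each with a called difference. Cyp2b9 fell by 2.23 with CA and was at 2.43 with UDCA, and Celsr1 was at 2.26 with CA and -0.75 with UDCA. Slides 3 and 4 held arrays of both groups. On slide 3 the CA array had the knockout in Cy3 and the UDCA arrays had it in Cy5. Differences within slides were taken after removing the dye effect of the reported fit, which was estimated from the arrays of all slides. Within slide 3 the diet and the dye cannot be told apart without that estimate, so its values are not a check free of other slides. With the slide as a block, slide 3 alone gives no estimate of the difference. For Cyp2b9 the difference was -4.31 with the slide as a block, -3.40 and -4.97 within slides 3 and 4, and for Celsr1 it was 3.18 with the slide as a block, 2.96 and 3.34 within slides 3 and 4. Cyp8b1 gave -3.14 with the slide as a block, -2.56 and -2.36 within slides 3 and 4, and Clec4f gave -3.63 with the slide as a block, -3.43 and -2.68 within slides 3 and 4. Over the 20 genes, 19 differences were called with the slide as a block. Bcl6, at 1.53 with the block, was the gene that missed the call there.

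Other genes were not shown to differ between the diets. The difference was 0.15 ± 0.38 for Cyp7a1 (95% interval -0.66 to 0.97; its other probe, also not called, at -0.84), -0.67 ± 0.36 for Slc10a1 (-1.43 to 0.09), -0.11 ± 0.22 for Nr0b2 (-0.57 to 0.35), -0.09 ± 0.35 for Abcb11 (-0.85 to 0.67), -0.53 ± 0.54 for Ccl2 (-1.68 to 0.61, and 0.08 without CA replicate 4) and -0.12 ± 0.22 for Lcn2 (-0.59 to 0.36). Timp1 missed the threshold at 0.51 ± 0.19 (adjusted p = 0.0532), whereas Krt19 (1.23 ± 0.28, adjusted p = 0.00485) and Mki67 (0.86 ± 0.25, adjusted p = 0.0185) were higher with CA. The probes of Col1a1 disagreed, the brighter one giving -0.48 ± 0.42 (adjusted p = 0.418) and the other a called difference of 1.03. The Abcb4 probes disagreed too, at 0.48 (adjusted p = 0.228) for the brighter probe and a called -0.95 for the other.

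Compared with other genes, the bile duct, matrix, chemokine, antigen presentation, B cell and cell division lists were higher with CA than with UDCA at camera's preset correlation, and with an estimated correlation camera called 0 of 35 lists (3 unadjusted). In that test the lists of macrophages, T and NK cells, neutrophils and interferon response were not shown to differ, although some of their members did. Cholangiocyte markers were higher in 13 of 20 cases and lower in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 0.000237, adjusted p = 0.365 with an estimated correlation), with a median of 0.998 (1.03 with the slide as a block, 1.42 and 0.70 within slides 3 and 4). Matrix genes were higher in 18 of 36 and lower in 0 (22 and 0 adjusted over the list alone; camera adjusted p = 0.000758, adjusted p = 0.365 with an estimated correlation), with a median of 0.63 (0.45 with the slide as a block, 0.999 and 0.50 within slides 3 and 4). The collagen gene Col8a1 was at 1.79 (1.73 with the block, 2.37 within slide 3 and 1.28 within slide 4). For stellate cell and portal fibroblast markers, 7 of 16 were higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.0230, adjusted p = 0.365 with an estimated correlation), median 0.34 (0.25 with the slide as a block, 0.74 and 0.43 within slides 3 and 4). Chemokines and cytokines were higher in 9 of 20 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00619, adjusted p = 0.365 with an estimated correlation), median 0.64 (0.60 with the slide as a block, 1.03 and 0.48 within slides 3 and 4). Cxcl16 was at 1.63 (1.47 with the block, 2.34 within slide 3 and 1.83 within slide 4). MHC class II genes were higher in 5 of 10 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00645, adjusted p = 0.365 with an estimated correlation), median 0.65 (0.42 with the slide as a block, 1.04 and 0.51 within slides 3 and 4). Cell division genes were higher in 8 of 30 (10 and 0 adjusted over the list alone; camera adjusted p = 0.0109, adjusted p = 0.365 with an estimated correlation), median 0.45 (0.31 with the slide as a block, 0.62 and 0.26 within slides 3 and 4). B and plasma cell markers were higher in 2 of 6 (2 and 0 adjusted over the list alone; camera adjusted p = 0.0429, adjusted p = 0.365 with an estimated correlation), median 0.46, 0.44 with the block, 0.80 and 0.33 within the slides. Of p53 targets and immediate early genes, 7 of 16 were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0358, adjusted p = 0.424 with an estimated correlation), median 0.61, 0.21 with the block, 1.15 and 0.13 within the slides. Macrophage and Kupffer cell markers split, 9 of 22 higher and 4 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.904). Ccr2 was at 2.70 (2.79 with the block, 3.56 within slide 3 and 2.10 within slide 4, its other probe, also called, at 0.84) and Vsig4 at -2.16 (-2.08 with the block, -2.65 within slide 3 and -1.38 within slide 4). T and NK cell markers gave 2 higher and 0 lower in 12 (2 and 0 adjusted over the list alone; camera adjusted p = 0.553; median 0.25, 0.14 with the block, 0.27 and 0.16 within the slides). Interferon genes gave 7 and 0 in 18 (7 and 0 adjusted over the list alone; camera adjusted p = 0.183; median 0.18, 0.47 with the block, 0.22 and 0.51 within the slides; called up by fry, adjusted p = 0.0225), and neutrophil markers 0 and 0 in 3 (0 and 0 adjusted over the list alone; camera adjusted p = 0.905; median 0.38, 0.54 with the block, 1.20 and 0.47 within the slides). Fewer members of most of these lists were called with the slide as a block. There 11 of 36 matrix genes, 3 of 16 stellate cell and portal fibroblast markers, 3 of 30 cell division genes and 11 of 20 cholangiocyte markers were higher and 0 lower. Chemokines and cytokines gave 7 higher and 1 lower, MHC class II genes 2 and 1, p53 targets and immediate early genes 4 and 0, interferon genes 4 and 0, and T and NK cell markers 0 and 0.

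Compared with other genes, metabolic and antioxidant lists were lower with CA than with UDCA at camera's preset correlation, and here too none was called with an estimated one. Glutathione and NRF2 antioxidant genes were lower in 12 of 21 cases and higher in 0 (0 and 14 adjusted over the list alone; camera adjusted p = 3.25e-09, adjusted p = 0.193 with an estimated correlation), with a median of -0.86 (-0.78 with the slide as a block, -0.95 and -0.75 within slides 3 and 4). Gstm4 was at -2.08 (-2.53 with the block, -1.86 within slide 3 and -2.07 within slide 4) and the glutathione synthesis gene Gclc at -1.75 (-1.95 with the block, -1.61 within slide 3 and -1.69 within slide 4). P450 genes were lower in 8 of 21 and higher in 0 (0 and 12 adjusted over the list alone; camera adjusted p = 2.37e-06, adjusted p = 0.365 with an estimated correlation), median -0.89 (-0.52 with the slide as a block, -1.37 and -0.56 within slides 3 and 4). Cyp2c55 was at -2.54 (-2.57 with the block and -2.21 within slide 3) and Cyp2b10 at -2.36 (-1.69 with the block, -2.49 within slide 3 and -1.37 within slide 4). Acute phase genes were lower in 9 of 23 and higher in 1 (1 and 9 adjusted over the list alone; camera adjusted p = 1.19e-05, adjusted p = 0.365 with an estimated correlation), median -0.56 (-0.40 with the slide as a block, -0.59 and -0.30 within slides 3 and 4). Saa3 was at -2.20 (-2.10 with the block, -2.09 within slide 3 and -2.33 within slide 4). Female-biased genes were lower in 7 of 12 and higher in 1 (2 and 8 adjusted over the list alone; camera adjusted p = 0.000655, adjusted p = 0.365 with an estimated correlation), median -0.96 (-0.82 with the slide as a block, -0.34 and -0.42 within slides 3 and 4). Male-biased genes were lower in 3 of 14 (0 and 3 adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.365 with an estimated correlation), median -0.42 (-0.11 with the slide as a block, -0.83 and -0.10 within slides 3 and 4). Fatty acid synthesis genes were lower in 7 of 18 (0 and 7 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.365 with an estimated correlation), median -0.48 (-0.92 with the slide as a block, -1.25 and -0.22 within slides 3 and 4). Fatty acid oxidation genes were lower in 5 of 22 (0 and 5 adjusted over the list alone; camera adjusted p = 0.000758, adjusted p = 0.365 with an estimated correlation), median -0.51 (-0.46 with the slide as a block, -0.55 and -0.40 within slides 3 and 4). Cholesterol synthesis genes were lower in 4 of 25 and higher in 1 (1 and 3 adjusted over the list alone; camera adjusted p = 0.000709, adjusted p = 0.365 with an estimated correlation), median -0.38 (-0.60 with the slide as a block, -0.68 and -0.59 within slides 3 and 4). Uptake carriers were lower in 2 of 7 and higher in 1 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0167, adjusted p = 0.365 with an estimated correlation), median -0.67 (-1.14 with the slide as a block, -1.05 and -1.07 within slides 3 and 4). Bile acid synthesis genes were lower in 3 of 15 and higher in 1 (1 and 4 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.365 with an estimated correlation), and their median turned from -0.33 to 0.15 with the slide as a block and was -0.96 and 0.21 within slides 3 and 4. Complement and coagulation genes were lower in 5 of 25 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00187, adjusted p = 0.365 with an estimated correlation), and their median likewise turned sign with the block (-0.30, 0.08 with the block, -0.50 and 0.24 within the slides). Mbl2 is again among the 5. With the slide as a block 10 antioxidant genes, 8 P450 genes, 8 cholesterol synthesis genes, 4 uptake carriers, 5 female-biased genes and 3 complement and coagulation genes were lower.

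In the difference test, exporters (camera adjusted p = 0.0358, adjusted p = 0.365 with an estimated correlation; median -0.09, -0.23 with the block, -0.08 and 0.07 within the slides) were also lower with CA. So were receptors and sensors (camera adjusted p = 0.0391, adjusted p = 0.365 with an estimated correlation; median -0.17, -0.35 with the block, 0.07 and -0.50 within the slides) and pancreas genes (camera adjusted p = 0.0120, adjusted p = 0.365 with an estimated correlation; median -1.64, -2.62 with the block, -1.04 and -0.56 within the slides). Their called members were 4 lower and 1 higher in 11, 3 and 0 in 11, and 3 and 0 in 4 (1 and 5 adjusted over the list alone, 0 and 3 adjusted over the list alone and 0 and 4 adjusted over the list alone). The pancreas genes were lowest on CA arrays 3 and 4, as given above. Hepatocyte genes (0 and 0 of 22; 0 and 0 adjusted over the list alone; camera adjusted p = 0.171; median -0.19, 0.21 with the block, -0.29 and 0.26 within the slides) and endothelial markers (2 higher and 1 lower of 13; 2 and 1 adjusted over the list alone; camera adjusted p = 0.659; median 0.13, 0.08 with the block, 0.04 and 0.52 within the slides) were not shown to differ.  Median centring in place of loess left 781 probes (661 higher and 120 lower), a slide term added to each ratio, chosen after the data were seen, left 1993, and leaving out the 3 arrays with a dim red channel, also chosen afterwards, left 3742. The fit with the added slide term drew the difference from slides 3 and 4 alone. With the slide as a block, that is a separate dye effect for each slide, the count was 4062.

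The ratios to wild type of the CA-fed and UDCA-fed groups were related across probes. Both groups lacked Abcb4, and no knockout liver without either bile acid was measured. A shared effect of the knockout and a shared effect of the diets therefore cannot be told apart here. Of the probes called with UDCA, 2692 were higher with both diets, against 1122 for independent lists of the same sizes, and 1463 were lower with both, against 462. Those shared calls made up 81.7% of the higher and 81.0% of the lower UDCA calls. Across the 21688 probes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.758 ± 0.0566 (jackknife standard error over arrays), a Spearman correlation of 0.703, a covariance of 0.280 and the same sign in 74.7%, and the slope of UDCA on CA was 0.437. The labels do not say whether the groups shared wild-type livers. Unchanged groups simulated against shared wild-type livers gave a correlation of 0.499, a covariance of 0.0111 and the same sign in 66.7%. That simulation gave both sides of a ratio the same spread and shared every wild-type value. Its correlation and same-sign share follow from this setting rather than from the data. Between CA arrays with the knockout in Cy5 and UDCA arrays with it in Cy3 the correlation was 0.451 and the covariance 0.230, and with the dyes the other way round they were 0.399 and 0.175.

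**Figure D3:**
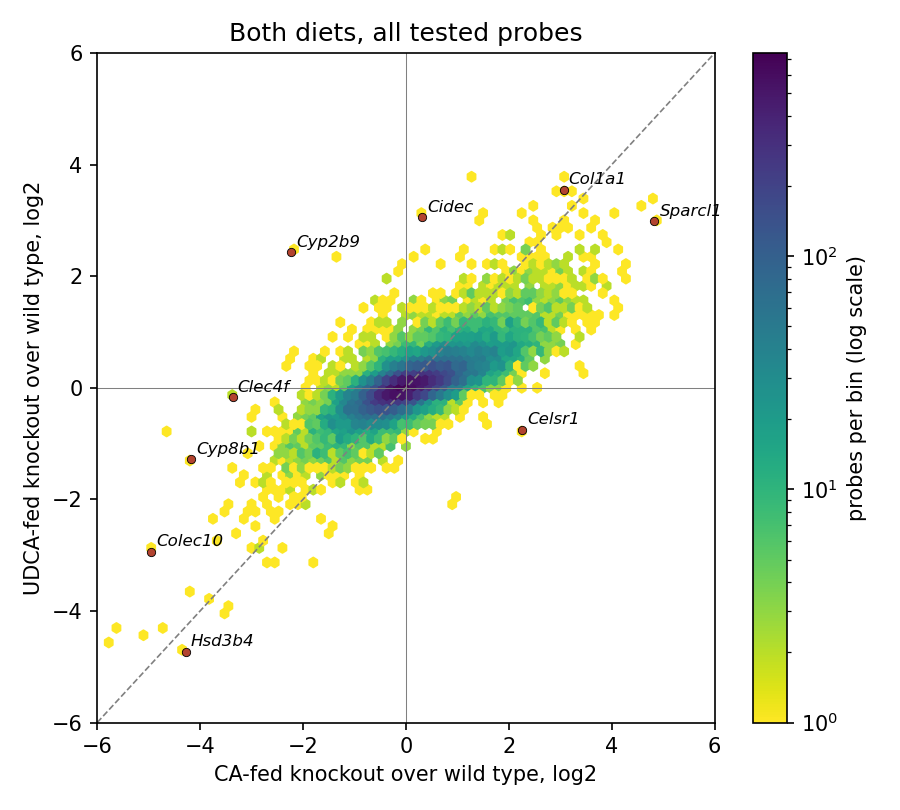
Log2 ratio of knockout over wild type with UDCA (vertical axis) against that with CA (horizontal axis) for all 21688 tested probes, shaded by the number of probes per bin on a log scale, with 9 named genes as dots and the line of equal effects dashed. Most probes lie nearer to the horizontal axis than the dashed line does, with a slope of 0.437, while Hsd3b4 lies on the other side of it (-4.28 and -4.74).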

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

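Single arrays were compared with the rest of their group by Dixon's test, for the 145 genes named in the text, and opposite movement under the diets was taken from the test of the difference, as fixed before the data were examined; the look at UDCA array 6 and at Mbl2 came after the values were seen. Dixon's test marks about 1 in 20 groups by chance, and of 290 groups it marked 21, against 14.5 from chance. In the CA group 1 array stood apart, as the gap over the range, for Ccl2 (0.743, array 4), Sox9 (0.629, array 6), Lyz1 (0.670, array 4), Cyp2c54 (0.667, array 2), Gstm4 (0.643, array 3) and Bicc1 (0.627, array 4). In the UDCA group array 6 stood apart for Pf4 (0.640), Ccr2 (0.869), Ddr1 (0.767), Epcam (0.649), Cx3cl1 (0.635), Pdgfra (0.772), Tmem130 (0.722), Krt23 (0.734), Slc51b (0.718), Gstm4 (0.716), Oasl2 (0.709), Rragd (0.727) and Ccl20 (0.669), and other arrays for Ces2c (0.729, array 5) and C8b (0.635, array 2).

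UDCA array 6 was thus marked for 13 of the 21 groups, most of them with a ratio above those of the other UDCA arrays and nearer to those of the CA group. Its bile duct markers had a median of 2.39, against 0.45 to 1.42 on the other UDCA arrays. It was the array of slide 5, so the liver and the slide cannot be told apart. Without UDCA replicate 6, 4232 probes were called with UDCA and 6835 in the difference, so this array may have made the diets look more alike.

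Several genes moved in opposite directions with the diets, each with a called difference. Higher with CA and lower with UDCA were Bcl6 (2.97), Bmf (2.90) and Celsr1 (3.01), with CA minus UDCA in brackets. Lower with CA and higher with UDCA were Saa3 (-2.20), Cd5l (-2.78), Cyp2b13 (-3.64), Cyp2b9 (-4.66), Gclc (-1.75), Slco1a4 (-1.89), Vsig4 (-2.16) and Gstm4 (-2.08). Genes of resident macrophages (Cd5l and Vsig4), of glutathione synthesis and conjugation (Gclc and Gstm4), of the acute phase (Saa3) and of steroid hydroxylation (Cyp2b9 and Cyp2b13) stand on that side. The other probe of Bmf, not called, gave 0.34 in the difference and that of Cyp2b13, not called, gave -0.09 with CA, so the opposite movement of Bmf and Cyp2b13 rests on 1 probe each.

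A call of Mbl2, a lectin of the complement system, was set aside. It was called lower with CA at -1.68 ± 0.50, although the 3 CA arrays with a value, all with the knockout in Cy5, were higher than wild type (1.09, 0.55 and 0.40). The fit reached a negative value through the dye effect of the UDCA arrays. Such calls were few, as 5 of 12930 probes called with CA and 2 of 5101 called with UDCA had values in a single dye orientation of that group.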

How the results depend on the processing

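The alternatives were fixed before the data were examined, except for leaving out the 3 dim arrays, the additive slide term and setting saturated spots to missing, which were chosen after the data were seen. No probe called under an alternative had the opposite direction to its call in the reported fit. Median centring in place of loess left 6094 probes with CA, 1971 with UDCA and 781 in the difference, and 247 calls of genes under the naming rule in place of 403. The cause was not tested. The strict filter left 6977 probes with CA and 3230 in the difference, because 12016 probes were tested. With CA 3199 were then higher and 3778 lower, and in the difference 1467 and 1763. The additive slide term left 1993 probes in the difference, of which 1852 were called in the reported fit, and leaving out the dim arrays left 3742, of which 3556 were, with fewer arrays in the fit. Camera with an estimated correlation called 0 gene lists in place of 65, as it allows for the correlation measured within each list.

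The counts stayed within 1.5 times the reported ones in the other settings. Leaving out single arrays gave 11803 to 13329 probes with CA, 3944 to 5580 with UDCA and 4399 to 6835 in the difference. Averaging a possible dye-swap pair gave 11881 to 13506, 4134 to 5647 and 4187 to 7003. The slide as a block gave 11223, 4044 and 4062, of which 10285, 3440 and 3325 were among the reported calls, and the series table gave 14291, 5660 and 7521. With CA the series table had 6980 higher and 7311 lower, so the excess of higher probes did not hold there. The correlation between the ratios to wild type of the CA and UDCA groups lay between 0.702 and 0.774 in all settings.

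Among the values of genes named in the text, 7333 of 7549 kept their side of the threshold and direction, 193 lost a call, 19 gained one and 4 turned. These were F9 with UDCA to 0.0398 (median centring), Mbl2 with CA to 0.68 (no dye term), Mbl2 in the difference to 1.45 (no dye term) and Mbl2 in the difference to 0.0530 (a possible dye-swap pair averaged). For Mbl2 the missing values in one dye orientation are the cause, and for F9 the cause was not tested. Of 65 called list tests, 39 kept their call in all settings with the preset correlation, and in camera's test none changed direction, although the medians of bile acid synthesis and of complement and coagulation turned sign in the difference with the slide as a block. The replicate number as a block gave 4803 probes in the difference. Arrays of the same number in the diet groups had residual correlations of -0.213, -0.141, 0.135, -0.145, -0.209 and -0.546. These values give no sign that the numbers pair the arrays. The dye effect shared by the groups in the fit lowers such correlations, so pairing was not excluded. Fewer spots were well above background in red (31.6% to 62.4%) than in green (41.6% to 68.4%) on 8 of the 12 arrays.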

Other observations

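The tests in this part on the clock, on sex-biased genes and on cell types were chosen after the results were seen, and the counts of other groupings of the arrays were fixed before. Clock genes moved in both knockout groups. Arntl, an activator of the clock, rose at 1.10 with CA and 2.02 with UDCA, while the repressor gene Per2 (-1.14 and -0.97), Ciart (-1.71 and -2.34) and the output gene Tef (-1.19 and -1.64) fell. Of 12 clock genes 9 fell and 1 rose with CA (1 and 10 adjusted over the list alone; camera adjusted p = 0.00121, adjusted p = 0.185 with an estimated correlation), and 8 fell and 2 rose with UDCA (2 and 9 adjusted over the list alone; camera adjusted p = 0.000197, adjusted p = 0.0898 with an estimated correlation). In the difference 4 were lower and 2 higher (2 and 4 adjusted over the list alone; camera adjusted p = 0.310).

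Stress and blood genes moved less uniformly. In the unfolded protein response 5 of 13 genes fell and 2 rose with CA (camera adjusted p = 0.0879), with Chac1 at -0.96 and the asparagine synthetase gene Asns at 0.98, and with UDCA 2 fell and 1 rose (camera adjusted p = 0.303), the median of 0.00425 and the mean of -0.08 differing in sign. Metallothionein and heat shock genes gave 3 falls and 2 rises in 10 with CA (camera adjusted p = 0.379; fry pointed up and the median and mean down) and 2 and 1 with UDCA (camera adjusted p = 0.0991). The chaperone gene Hspa1a fell with both diets (-2.24 and -1.57), and in the difference the list's median of -0.04 and mean of 0.22 differed in sign (camera adjusted p = 0.811). Of 6 red cell and platelet genes 3 fell and 1 rose with CA (camera adjusted p = 0.249) and 2 and 1 with UDCA (camera adjusted p = 0.173). The heme synthesis gene Alas2 was at -1.27 and -0.99 and the platelet gene Pf4 at 2.11 and 1.04. Of 2 adipose genes measured, Cidec rose with UDCA (3.06) and Fabp4 with both diets (1.69 and 0.90), and the list was called with UDCA (camera adjusted p = 0.00777, adjusted p = 0.120 with an estimated correlation) but not with CA (camera adjusted p = 0.311).

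A candidate explanation for the clock genes is that knockout and wild-type livers stood at different phases of the clock when they were taken. In both groups together 19 calls of clock genes (9 with CA and 10 with UDCA, among the same genes) followed the known phase, but this decides nothing. The phases were looked at after these genes had been seen to move, 2 genes of the rising phase were measured and 1 was called with CA, and the groups may share wild-type livers. A dye or slide effect is argued against by the lowest difference between the opposite phases over the 12 arrays, which was 1.16. Whether hours of sampling or the disease shifted the clock stays open, because the labels give no hour.

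Sex-biased genes moved as well, male-biased ones such as Hsd3b5 falling with both diets (-3.48 and -4.10) and female-biased ones such as Cyp2a4 parting between them (-2.22 and 0.49). Cyp2a4 was not among the named genes with calls in opposite directions, while Cyp2b9 was (-2.23 and 2.43). Female animals among the knockouts are argued against by the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, whose median ratio on the lowest array was -0.61, where a female knockout against a male wild type would leave hardly any signal. The 4 probes of Xist, a gene chosen after the values were seen, were above background on 0 of 12 arrays. The slides were not excluded as a source of the difference between the diets. Over all measured female-biased genes its median was -0.96, and within slides 3 and 4, with 1 CA array each, it was -0.34 and -0.42. On single arrays the dye also counted, as the median of the male-biased genes lay between -2.58 and -0.98 with the knockout in Cy3 and between -1.86 and 0.55 with it in Cy5. Each diet group held 3 arrays of either orientation and the fit had a dye effect. A dye effect that adds to the log2 ratio therefore cancels in the means of the groups where no value is missing. Saturation is not such a shift and need not cancel. Of the 14 male-biased genes, 10 were saturated on 3 or more CA arrays and 8 on 3 or more UDCA arrays. Saturated spots per array ranged from 549 to 2590 in green and from 0 to 417 in red. The share of saturation in the difference between the orientations was not tested. A change in the hormone signals that set these genes may lie behind the pattern and was not tested.

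Markers of bile ducts and matrix rose with both diets. A smaller share of hepatocytes alone would raise the markers of all other cell types alike, but with CA the median of the bile duct markers exceeded that of the endothelial markers by 2.37 (permutation p = 0.00259), and with UDCA by 1.16 (permutation p = 0.0144). The permutation exchanged genes between the lists, and genes move together on an array, so its p does not measure the spread between livers. On every array the bile duct median lay above the endothelial median, the lowest being 0.45 against 0.04 on UDCA array 5. A dye or slide effect is argued against by the lowest median of the bile duct markers on any array, 0.45. More duct cells or more RNA per duct cell may each lie behind this and cannot be separated in whole liver.

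Chance as the source of the counts was tested by regrouping the arrays, on probes without missing values. For CA against wild type, 1 of 32 exchanges of knockout and wild type gave as many probes, namely the real one with 12330, and the highest of the others gave 5928. For UDCA it was 1 of 32, with 4755 against 7. For the difference it was 1 of 100 splits, with 5659 against 2. No other drawn split came near the real count. These splits drew arrays, so a dye-swap pair could be parted, and the 126 splits of the 10 livers were not run. Slides 1, 2 and 5 held a single diet each, so chance among livers was not excluded. An additive slide term left 1993 probes in place of 5858, 1852 of them also called in the reported fit and 0 in the opposite direction. In that fit the difference came from slides 3 and 4 alone. Arrays of the other slides carried no weight for it, except CA arrays 3 and 4 through the dye effect. In the lower count, the loss of those arrays and a slide effect cannot be told apart. For those 1852 an additive slide effect alone is argued against, on slides with 1 CA array each, and for the others it stays open. Within slides 3 and 4, with 1 CA array each, 99.8% and 98.8% of called probes kept their sign, but those arrays helped to call them. On slide 3 the diets stood in opposite dyes, so its share also relies on the dye effect of the reported fit. Against wild type 1 pair of arrays per group came from the same liver, and the 5 livers leave 16 exchanges, too few for a share under 0.05. The exchange with 5928 probes had turned 1 of the 6 arrays.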
